A study of Mus musculus with 22 samples.

How the data were processed

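Gene expression was measured by RNA sequencing in 22 libraries of primary mouse microglia, the resident macrophages of the brain. Per the labels' protocols, mixed glia were grown from the cortex of newborn C57BL/6 mice and the microglia were then shaken off, and polyadenylated RNA from Trizol extracts was sequenced on an Illumina instrument. All libraries came from cultures given lipopolysaccharide (LPS), a bacterial cell wall component that activates microglia, at 100 ng/ml for 24 h. The groups were LPS alone (n = 3), LPS with bafilomycin A1 at 10 nM (LPS+Baf A1, n = 5), LPS with CLA at 50 nM (LPS+CLA, n = 6), LPS after 48 h of transfection with an siRNA against Atg5 at 50 nM (LPS+siAtg5, n = 5) and LPS+dNC (n = 3), which the design text names as the comparator of LPS+siAtg5. The labels do not spell out CLA or dNC, and the dose of the control siRNA is not given in the sources used here. Each library was assigned to its group by its title.

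The deposited values are FPKM, fragments scaled to the length of the gene and the mapped fragments of the library, with 1 value per gene symbol rounded to 2 decimals, per the file headers for 19 columns. The headers of the 3 LPS+dNC columns name no unit, and these were read as FPKM from their range and sums. Per the submitters' processing notes, the authors used CASAVA 1.7, fastp 0.18.0, Bowtie2 2.2.8, HISAT2 without a stated version and StringTie 1.3.1. The order of these tools, the genome build and the annotation are not given in the sources used here. The series table held 15726 lines for 15725 symbols, and the 22 files of single libraries were identical to their columns. Plin2 had 2 lines that differed only in the LPS+dNC columns, with group means of 929.78 and 0.25 FPKM, and the first line was used. In all, 191 genes were at 0 in every library. No read counts were used here, so the depth of each library is unknown and no counting interval can be given for any value. The sums of FPKM ranged from 469750 to 575125 and the smallest value above 0 was 0.01.

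Values were analysed as log2(FPKM + 1), so a fold change is on that scale and understates the change of genes with low values. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 11070. One linear model with 5 group means was fitted to all 22 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options, 17 residual degrees of freedom), and each comparison was a contrast of that model with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The design had been written for either counts or normalized values, and the branch for normalized values was used. The comparisons were LPS+Baf A1 against LPS, LPS+siAtg5 against LPS+dNC and LPS+CLA against LPS, which the design text names, and in addition the difference between the Baf A1 and siAtg5 effects, LPS+CLA against LPS+Baf A1, and LPS+dNC against LPS. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

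In addition, 28 gene lists were tested with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. They covered autophagy machinery, V-ATPase subunits, lysosomal proteins, pro-inflammatory mediators, interferon-stimulated genes, anti-inflammatory and repair markers, remyelination-linked secreted factors, PPAR and LXR target genes, fatty acid synthesis and desaturation, phospholipase A2 and linoleic acid metabolism, cholesterol synthesis, homeostatic and disease-associated microglia markers, phagocytosis, stress responses, hypoxia and glycolysis, iron handling, NRF2 target genes, cell cycle, mitochondrial respiratory chain, antigen presentation, and markers of astrocytes, oligodendrocyte lineage, neurons, fibroblasts with mural and endothelial cells, border macrophages with monocytes, and neutrophils with lymphocytes. A list needed at least 5 tested members, which left out the neutrophil and lymphocyte list with 2. Each test was repeated with a correlation estimated from the data for each list, and with fry from limma, which tests whether the genes of a list move one way on balance and does not compare the list with other genes.

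The groups, the tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except the 3 alternatives named as added. The rule named, for each of the 3 main comparisons, Atg5, Pparg, Fads1, Fads2, Tnf, Il1b, Nos2 and Arg1, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups' libraries, leaving out predicted-gene names, and of each list up to 4 members per direction with the smallest adjusted p where the list was called and up to 2 where it was not. For the other contrasts it named 3 genes per direction. Where genes named together are fewer than the rule gives, the text holds a part of them, and some are not reported here. For the difference between the Baf A1 and siAtg5 effects this rule gave no gene, and the genes given there were named by the rule in the main comparisons.

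Positions are from the GENCODE M21 annotation of GRCm38, to which 15720 symbols were matched. Transcripts of this annotation were compared to find genes that share over 20% of their 31-base sequences with another gene, of which there were 1941. Values of such genes are uncertain, because the rule for shared reads is not given in the sources used here. The strand rule is likewise not given, so reads of overlapping genes on opposite strands cannot be told apart.

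The calculation was tested on simulated data for the 11070 genes with 200 changed. Of genes changed by 0.5 and by 1 on the log2 scale it recovered 84% and 99% for LPS+Baf A1 against LPS, 80% and 98% for LPS+siAtg5 against LPS+dNC, and 88% and 98% for LPS+CLA against LPS. The share of false calls among all calls was 4.2%, 6.3% and 4.6%, no change had the wrong sign (0), and 0 lists were called. The simulated values were independent between genes and held no library apart from its group. The 0 lists therefore say nothing about list calls where genes are correlated, and the other shares hold for that setting only. The alternatives were median-of-ratios scaling, quantile normalization, no filter, a filter at 5 FPKM, array weights, the replicate number as a block, a pseudocount of 0.1, a fit of only the 2 groups compared, estimated correlations, fry, and leaving out each library in turn. After the data were seen, the added alternatives left out LPS replicate 3, LPS+dNC replicate 1 and LPS+CLA replicate 2 together, left out the genes that share sequence, and used the LPS libraries as the control of LPS+siAtg5. For lists, calls and ranges of adjusted p under the alternatives are for camera at the preset correlation. Estimated correlations and fry are reported apart from these ranges. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, with numpy 2.4.6 and pandas 2.3.3. The protocols also name T0070907, for which no sample was used here.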

Results

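The series asked how 2 ways of suppressing autophagy, and CLA, changed gene expression in mouse microglia that had been activated with LPS. Primary microglia gave 22 sequenced RNA libraries, in groups of 3 (LPS), 5 (LPS+Baf A1), 6 (LPS+CLA), 3 (LPS+dNC) and 5 libraries (LPS+siAtg5). No culture without LPS was analysed here, so every comparison is between cultures given LPS. Values are FPKM, read counts were not used here, and the depth behind each value is unknown.

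The LPS+siAtg5 libraries stood apart from all others. Their median gene was at 4.53 to 4.8 FPKM and 10752 to 10908 genes reached 1 FPKM, against medians of 2.62 to 3.25 FPKM and 9112 to 9571 genes in the other 17 libraries. Correlations between libraries of a group ranged from 0.9845 to 0.9979 across genes. A single library lay apart from its group in 3 groups. The SD across genes of the log2 difference to its group mates was 0.273 to 0.284 for LPS replicate 3 against 0.158 between the other LPS libraries, 0.351 to 0.388 for LPS+dNC replicate 1 against 0.187, and 0.267 to 0.273 for LPS+CLA replicate 2 against 0.139 to 0.156. No such library was seen in LPS+Baf A1 (0.154 to 0.179) or LPS+siAtg5 (0.138 to 0.173).

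**Figure D1:**
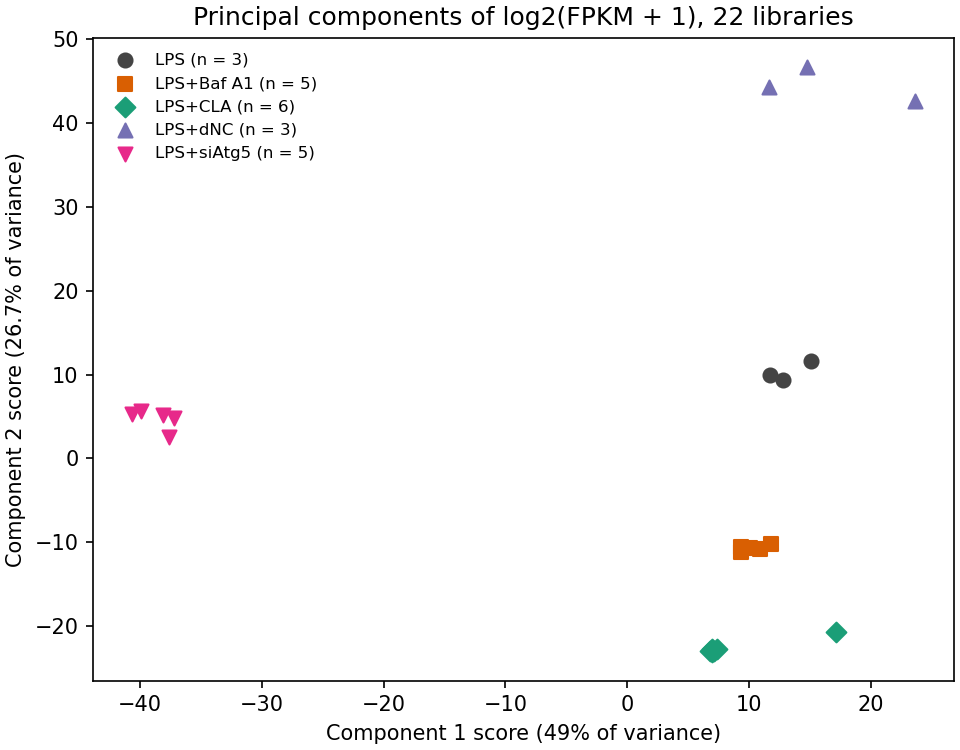
Scores of the 22 libraries (points, coloured by group) on the first and second principal component of log2(FPKM + 1), with 49% and 26.7% of the variance. Scores are scaled to the same length on both components, so they have no unit and their size cannot be compared between components. Component 1 separates LPS+siAtg5 (scores of -40.62 to -37.16) from all other groups (6.76 to 23.59), and component 2 places LPS+dNC (42.64 to 46.65) far from LPS (9.41 to 11.65).

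Baf A1 is an inhibitor of the vacuolar proton pump, and it blocks the acidification of lysosomes and the degradation of autophagosomes. With Baf A1, microglia held less mRNA of the interferon response and more of interleukin-1, glycolysis, antioxidant defence and cholesterol synthesis than with LPS alone. Except for interleukin-1, which rests on single genes, these were calls of gene lists at a preset correlation, and none held with an estimated one (adjusted p = 0.25, 0.3, 0.084 and 0.72 in this order). Il1b (chromosome 2, 129364570 to 129371139 on GRCm38), which encodes the cytokine interleukin-1 beta, rose from 971.3 ± 87.8 (SD, n = 3) to 3551 ± 338 FPKM (n = 5), a log2 change of 1.87 (SE 0.15, limma adjusted p = 9.38e-10). Ifit2 (chromosome 19, 34550694 to 34576419), an antiviral gene induced by interferon, fell from 920.5 ± 40.5 to 267 ± 19.2 FPKM (log2 change -1.79, SE 0.086, adjusted p = 1.62e-13). Tnf, at 239 FPKM against 227 (log2 change 0.09, adjusted p = 0.623), was not called, nor was Nos2, the inducible nitric oxide synthase, at 226 ± 11.6 against 187 ± 30.3 FPKM (log2 change 0.28, adjusted p = 0.142).

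The genes with the largest rises with Baf A1 included matrix metalloproteinases and chemokines. Mmp3, a matrix metalloproteinase, went from 1.06 ± 0.368 to 22.6 ± 3.96 FPKM (log2 change 3.52, SE 0.3, adjusted p = 3.31e-09), Mmp12 from 47.9 ± 2.41 to 349 ± 52.4 FPKM (2.83), and Susd2 from 0.807 ± 0.242 to 12.4 ± 1.2 FPKM (2.89, SE 0.11, adjusted p = 2.75e-15). The neutrophil-attracting chemokines Cxcl3 and Cxcl1 rose by 2.78 and 2.48 on the log2 scale, the cytokine gene Il1a by 2.38, from 147 ± 16.4 to 776 ± 111 FPKM, and Igfbp7 by 2.76. S100a4 rose by 2.6, but 49.2% of its sequence is shared with another gene and its value is uncertain. Among the largest falls were Ly6a (-3.31, SE 0.18, adjusted p = 1.27e-12), Slfn4 (-3.11), Ms4a14 (-2.93), Pde1b (-2.62), Rsrp1 (-2.36), Phf11c (-2.31) and the interferon-inducible GTPase gene Iigp1 (-2.09, from 189 ± 16.4 to 43.7 ± 3.76 FPKM). Of these, Ly6a and Slfn4 share 31.9% and 20.9% of their sequence with other genes. Of the other genes fixed in advance, Atg5 rose by 0.28 (SE 0.048, adjusted p = 3.29e-05), while Pparg (-0.36, adjusted p = 0.22), Fads1 (-0.02, adjusted p = 0.914), Fads2 (0.27, adjusted p = 0.437) and Arg1 (0.24, adjusted p = 0.7) were not called.

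Among the fixed lists, interferon-stimulated genes fell with Baf A1. Of 34 tested members 32 fell and 1, Bst2, rose (0.23), and Oas2 went from 108 ± 4.95 to 28.6 ± 0.679 FPKM (-1.88). The list's median minus that of all genes was -0.75 (camera adjusted p = 5e-17, adjusted p = 0.25 with an estimated correlation). Bst2 was no longer called without LPS replicate 1 (0.15). Antigen presentation genes, which also depend on interferon, fell in 12 and rose in 3 of 17 (median minus all genes -0.33, adjusted p = 0.0078, adjusted p = 0.72 with an estimated correlation). The regulator Nlrc5 was at 29.7 against 57.7 FPKM, while H2-Ab1, a class II gene, rose from 2.17 to 11.6 FPKM. That list's adjusted p ranged from 0.000862 to 0.0924 over all alternatives at the preset correlation. It was lost without LPS replicate 3 (adjusted p = 0.0674) and without genes that share sequence (adjusted p = 0.0924). Its median minus all genes was then -0.28 and -0.31.

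Glycolysis and hypoxia genes rose in 25 and fell in 1 of 33 with Baf A1. Ldha, which makes lactate, went from 289.5 ± 26.4 to 931 ± 20 FPKM (log2 change 1.69, SE 0.078, adjusted p = 8.6e-14) and Tpi1 from 183 ± 25.8 to 524 ± 13.8 FPKM (1.52). The list median was 0.9 above all genes (camera adjusted p = 4.54e-10, adjusted p = 0.3 with an estimated correlation). NRF2 target genes, part of antioxidant defence, rose in 21 and fell in 3 of 25 (median minus all genes 0.84, adjusted p = 6.63e-08, adjusted p = 0.084 with an estimated correlation). Catalase (Cat) was at 54.7 ± 2.26 against 23 ± 0.927 FPKM and Pgd at 242 against 124 FPKM, and Osgin1 (-0.8) was among the falls. Of 37 respiratory chain genes 36 rose and 0 fell, such as Atp5a1 at 216 against 144 FPKM (0.38, adjusted p = 3.96e-08, adjusted p = 0.72 with an estimated correlation). Cholesterol synthesis genes rose in 17 and fell in 0 of 24 (0.41, adjusted p = 0.00224, adjusted p = 0.72 with an estimated correlation). Among them, Mvd rose by 0.95 and Lss by 0.48. Fatty acid synthesis and desaturation genes rose in 14 and fell in 2 of 27 (0.27, adjusted p = 0.0078, adjusted p = 0.72 with an estimated correlation). The members with the smallest adjusted p act in acetyl-CoA supply, thioester hydrolysis or chain elongation, such as Acss2 (1.3), Acot7 (1.39, 43.1 against 15.9 FPKM) and Hacd3 (1.1). The desaturase genes Fads1 and Fads2 were not called.

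The lists on autophagy and lysosomes went both ways with Baf A1 and were not called. However, the lysosomal list was called without a filter on low values (adjusted p = 0.0337). Its range was 0.0337 to 0.358 over all alternatives at the preset correlation. Autophagy genes rose in 17 and fell in 9 of 43, with Wipi1 up (0.79) and the cargo receptor Optn down (-0.74). V-ATPase subunits, the pump that Baf A1 inhibits, rose in 5 and fell in 6 of 18, with Atp6v1e1 at 0.48 and Tcirg1 at -0.7. Lysosomal genes rose in 21 and fell in 9 of 44, with Ppt1 at 0.62 and Ctss at -0.46. Pro-inflammatory mediators rose in 16 and fell in 6 of 34, with Il12b up 2.37 and Ccl7 down from 1433 to 688 FPKM (-1.04). That list was not called (median minus all genes 0.18, adjusted p = 0.106), but it was called as higher without a filter (adjusted p = 0.0354), with array weights (0.0102), with only the 2 groups fitted (0.0384), without LPS replicate 3 (0.0393) and without the 3 libraries that lie apart (0.0023), within a range of 0.0023 to 0.304. In the lists on repair and lipids, rises and falls numbered 3 and 8 of 14 for anti-inflammatory and repair markers (Il10 -0.92), 4 and 4 of 19 for remyelination-linked factors (Apoe -0.92), 14 and 2 of 25 for PPAR target genes (Hadhb 0.53), 5 and 10 of 18 for LXR target genes (Pltp -1.33), and 7 and 3 of 18 for phospholipase A2 and linoleic acid metabolism (Alox5ap 1.24). They were 7 and 11 of 23 for homeostatic microglia markers (Cst3 0.64, Mertk -0.58), 9 and 8 of 24 for disease-associated microglia markers (Ctsd 0.67) and 9 and 10 of 33 for phagocytosis (Fcgr4 -0.86). They were 13 and 12 of 31 for stress responses (Sdf2l1 1.76, Trib3 -1.13), 9 and 4 of 19 for iron handling (Hmox1 0.54) and 9 and 4 of 29 for the cell cycle (Tyms 1.17).

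Of the lists of markers of other cell types, that of neurons was called with Baf A1. Neuron markers fell in 7 and rose in 0 of 13, such as Dcx (-0.89) (median minus all genes -0.38, adjusted p = 0.0478, adjusted p = 0.86 with an estimated correlation). That call was lost with a filter of 5 FPKM (adjusted p = 0.289), a pseudocount of 0.1 (adjusted p = 0.145) and median-of-ratios scaling (adjusted p = 0.074). It was also lost without any 1 of the 3 LPS libraries (adjusted p = 0.0887, 0.0762 and 0.0688 without replicates 1, 2 and 3), without LPS+Baf A1 replicate 3 (adjusted p = 0.0723) or 5 (adjusted p = 0.0665) and without genes that share sequence (adjusted p = 0.0585). Over all alternatives at the preset correlation the adjusted p ranged from 0.00625 to 0.289. The list's median minus all genes was larger, not smaller, with the filter of 5 FPKM (-0.62) and the pseudocount of 0.1 (-0.92), and -0.34 to -0.4 under the other settings that lost the call. Astrocyte markers rose in 3 and fell in 1 of 15 (Gja1 1.48), oligodendrocyte markers in 2 and 1 of 8 and fibroblast, mural and endothelial markers in 5 and 1 of 14 (Fn1 2.13). Border macrophage and monocyte markers rose in 4 and fell in 3 of 13 (Mrc1 -1.11), and of 2 neutrophil and lymphocyte markers 1 rose (Camp 0.62). Adjusted over the list alone, the rises and falls differed for autophagy (17 and 10), lysosomal (21 and 10), interferon-stimulated (1 and 33), anti-inflammatory (4 and 8), disease-associated microglia (10 and 8) and stress response genes (14 and 12). They also differed for hypoxia (26 and 1), NRF2 (22 and 3), cell cycle (7 and 3) and oligodendrocyte genes (1 and 1) and were as given above for the other lists.

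Baf A1 changed 6395 of 11070 genes (limma with Benjamini-Hochberg adjustment), with 3619 up and 2776 down, and at least 2-fold in 223 and 223. The share of rises, 56.6%, was 49.8% under median-of-ratios scaling (3152 up and 3182 down) and 52.1% under quantile normalization. Of 27 lists, 8 were called by camera at the preset correlation. With an estimated one 0 were called (lowest adjusted p = 0.084, 3 lists with an unadjusted p under 0.05), and fry called 18. The LPS group holds 3 libraries, and its replicate 3 lies apart from the others.

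The knockdown comparison asked what loss of Atg5, a gene needed to form autophagosomes, did to LPS-treated microglia. Atg5 (chromosome 10, 44268358 to 44364291 on GRCm38) was at 13.1 ± 0.37 FPKM (SD, n = 5; 12.59 to 13.51) in LPS+siAtg5 and at 22.3 ± 1.7 FPKM (n = 3; 21.36 to 24.26) in LPS+dNC, 41.4% lower. The log2 change was -0.73 (SE 0.048, limma adjusted p = 4.05e-12), and a two-sided exact permutation test over the 56 splits of the 8 libraries gave p = 0.0179, the smallest it can give. Atg5 was at 20.1 ± 0.29 FPKM in LPS, 24.6 ± 0.77 in LPS+Baf A1 and 24.5 ± 1.1 in LPS+CLA, so LPS+siAtg5 was the lowest group and lay 34.9% below LPS. Under median-of-ratios scaling the log2 change was -1.03.

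With Atg5 knockdown, inflammatory and interferon-driven genes were far lower and genes of fatty acid synthesis and desaturation were higher, together with markers of astrocytes and other brain cells. As gene lists none of these held with an estimated correlation (lowest adjusted p = 0.091). Nos2 (chromosome 11, 78920787 to 78960254) fell from 538 ± 46.2 to 16.7 ± 1.94 FPKM (log2 change -4.94, SE 0.16, adjusted p = 8.12e-17), Il1b from 497 ± 101 to 197 ± 22.3 FPKM (-1.32, SE 0.15, adjusted p = 5.51e-08) and Tnf from 254 ± 27 to 159 ± 5.91 FPKM (-0.67, SE 0.14, adjusted p = 0.000146). Fads2 and Fads1, the desaturases that act on linoleic and alpha-linolenic acid and their products, rose from 2.94 ± 2.5 to 24.3 ± 1.58 FPKM (2.96, SE 0.29, adjusted p = 4.52e-09) and from 6.34 ± 1.88 to 21.1 ± 0.665 FPKM (1.62, SE 0.15, adjusted p = 1.77e-09). Both lie on chromosome 19, Fads2 at 10062765 to 10101746 and Fads1 at 10182888 to 10196877. Pparg, a nuclear receptor for fatty acids, rose from 0.59 ± 0.626 to 3.14 ± 0.431 FPKM (1.44, SE 0.25, adjusted p = 1.59e-05). Over the same libraries Gfap (chromosome 11, 102887336 to 102900912), the intermediate filament of astrocytes, rose from 2.14 ± 1.91 to 126 ± 7.81 FPKM (5.57, SE 0.29, adjusted p = 2.31e-13).

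**Figure D2:**
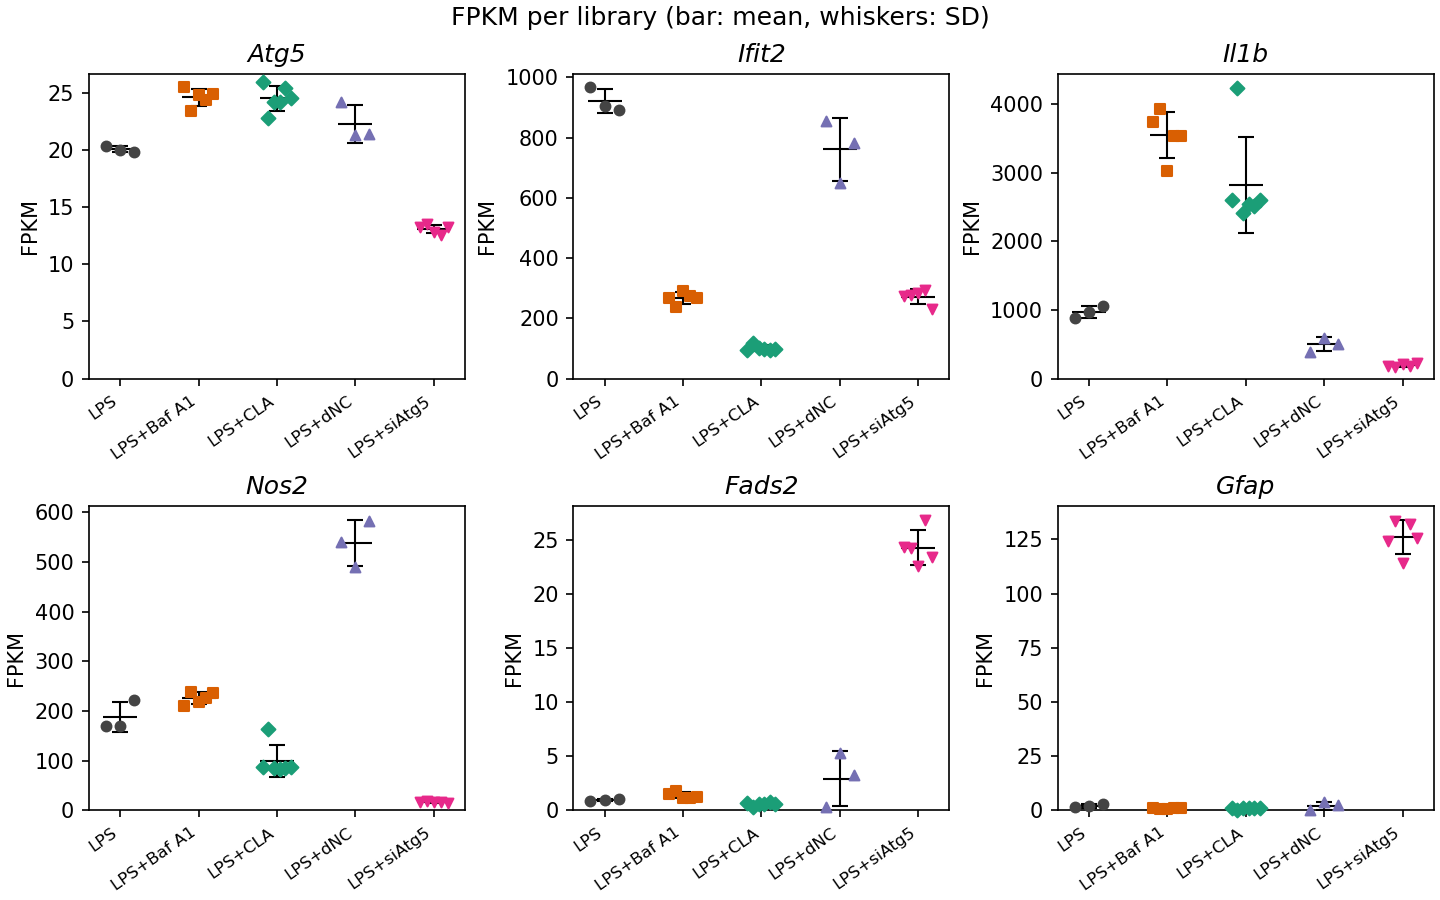
FPKM of Atg5, Ifit2, Il1b, Nos2, Fads2 and Gfap in each library (points) by group, with the group mean (bar) and SD (whiskers). Atg5 is lowest in LPS+siAtg5 (13.1 ± 0.37 FPKM), Ifit2 is below LPS (920.5 ± 40.5 FPKM) in LPS+Baf A1 (267 ± 19.2 FPKM) and LPS+CLA (101 ± 8.72 FPKM), and Fads2 (24.3 ± 1.58 FPKM) and Gfap (126 ± 7.81 FPKM) are highest in LPS+siAtg5.

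The genes with the largest rises with Atg5 knockdown included several astrocyte markers. Besides Gfap they were the water channel gene Aqp4 (0.337 ± 0.255 to 53.4 ± 2.06 FPKM, log2 change 5.36, SE 0.1, adjusted p = 1.44e-21), Igfbp2 (5.48), the glutamate transporter gene Slc1a3 (4.69), A2m (4.51), Clu (4.47) and Cnn3 (4.81, with 32% of its sequence shared). Rps6 rose by 5.6, but 45% of its sequence is shared and it was low in LPS+dNC alone, at 9.16 FPKM against 487 FPKM in LPS+siAtg5 and 368 FPKM in LPS. The largest falls were in Il19 (-6.08), Lilrb4a (-5.3, 56.1% shared), Nos2, Lyz1 (-4.5, 34.2% shared), Lipg (-4.42), Urah (-4.39), Olfr1033 (-4.28) and Dynlt1c (-4.1, 92.4% shared). Several of these did not fall against the LPS group, where the change was 0.24 for Il19, 0.13 for Lyz1, 0.1 for Olfr1033, -0.04 for Dynlt1c and -0.07 for Urah, and Lilrb4a (-1.15) and Lipg (-0.9) fell by less. Against LPS, Nos2 changed by -3.41, Gfap by 5.41, Aqp4 by 5.0, Fads2 by 3.69, Fads1 by 1.46, Pparg by 1.07, Il1b by -2.3 and Tnf by -0.5. Arg1 fell by 1.47 (adjusted p = 0.00841), a value that ranged from -2.58 without LPS+dNC replicate 1 to -0.80 without replicate 3 and was not called without replicate 2 (adjusted p = 0.0721) or 3 (adjusted p = 0.117), or with only the 2 groups fitted (adjusted p = 0.108), within a range of 1.25e-13 to 0.117 over all alternatives.

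Inflammatory gene lists fell with Atg5 knockdown. The values of lists are given relative to all genes, because the median change of all genes was 0.339, and 0.063 and 0.006 under median-of-ratios scaling and quantile normalization. Pro-inflammatory mediators fell in 29 and rose in 3 of 34, with the costimulatory gene Cd86 down from 48 ± 3.26 to 5.91 ± 0.627 FPKM (-2.83) and the chemokine gene Ccl4 from 1778 ± 73.2 to 374 ± 31.7 FPKM (-2.25). The list median minus all genes was -1.97 (camera adjusted p = 3.92e-16, adjusted p = 0.091 with an estimated correlation). The rises were Tlr2 (1.45), Marco (2.1) and Cxcl5 (0.66). Against LPS, Tlr2 and Marco differed by 0.16 and 0.14. Interferon-stimulated genes fell in 32 and rose in 2 of 34 (-1.38, adjusted p = 5.53e-20, adjusted p = 0.1 with an estimated correlation). Rsad2 went from 1705 ± 258 to 250 ± 26.3 FPKM (-2.76), Cxcl9 from 79 ± 10.9 to 4.51 ± 0.603 FPKM (-3.86) and Oas2 from 169 ± 6.52 to 32.1 ± 1.35 FPKM (-2.36). Xaf1, among the rises (0.21), turned to -0.11 under median-of-ratios scaling and to -0.15 against LPS. Antigen presentation genes fell in 15 and rose in 0 of 17 (-1.37, adjusted p = 5.57e-12, adjusted p = 0.091 with an estimated correlation). The immunoproteasome gene Psmb9 went from 201 ± 31.7 to 40.2 ± 2.59 FPKM (-2.29) and Tap1 from 251 ± 9.41 to 122 ± 3.68 FPKM (-1.04). Against LPS these falls were smaller, at -1.2 relative to all genes for pro-inflammatory mediators, -1.02 for interferon-stimulated genes and -0.73 for antigen presentation, and at -0.84 for Ccl4, -2.0 for Cxcl9 and -0.71 for Psmb9.

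Anti-inflammatory and repair markers fell in 8 and rose in 5 of 14 with Atg5 knockdown (median minus all genes -0.58, adjusted p = 0.0254, adjusted p = 0.29 with an estimated correlation). Among the falls with the smallest adjusted p, the interleukin-1 antagonist gene Il1rn went from 1835 ± 227 to 192 ± 14.7 FPKM (-3.25) and Socs3 from 386 ± 25 to 93.5 ± 5.03 FPKM (-2.03). Igf1 rose from 2.72 ± 0.552 to 36.1 ± 1.48 FPKM (3.33), Mrc1 by 1.53 and Clec7a by 1.58. Against LPS, Igf1, Mrc1 and Clec7a differed by -0.22, -0.93 and -0.31, and Il1rn by -1.9. The list's adjusted p ranged from 0.000128 to 0.304 over all alternatives at the preset correlation. It was lost under median-of-ratios scaling (adjusted p = 0.0621), quantile normalization (adjusted p = 0.304) and a filter of 5 FPKM (adjusted p = 0.0877). Its median minus all genes was then -0.56, -0.42 and -0.43, in this order. Hypoxia and glycolysis genes fell in 13 and rose in 8 of 33 (-0.43, adjusted p = 0.00374, adjusted p = 0.7 with an estimated correlation). Pfkfb3 went from 371 ± 26.1 to 67.3 ± 2.56 FPKM (-2.44), and the glucose transporter genes Slc2a1 (-1.49) and Slc2a3 (1.46) went in opposite directions. LPS+dNC stood high in Pfkfb3 and Slc2a1, which changed by -0.35 and -0.45 against LPS. That list was lost under quantile normalization (adjusted p = 0.168), without genes that share sequence (adjusted p = 0.0573) and against LPS (adjusted p = 0.462), within a range of 4.99e-05 to 0.462, and where the call was lost its median minus all genes was -0.28, -0.38 and -0.13, in this order.

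Lipid, antioxidant and cell cycle genes rose with Atg5 knockdown, in libraries that also held the raised astrocyte markers. Fatty acid synthesis and desaturation genes rose in 25 and fell in 1 of 27 (median minus all genes 0.57, adjusted p = 0.00374, adjusted p = 0.47 with an estimated correlation). With Fads1 and Fads2 they included the desaturase family gene Fads3, at 3.54 ± 0.475 against 0.273 ± 0.166 FPKM (1.84), and Acot7 (1.23). NRF2 target genes rose in 19 and fell in 3 of 25 (0.55, adjusted p = 0.0271, adjusted p = 0.47 with an estimated correlation). Cat was at 70 ± 2.85 against 23.3 ± 2.03 FPKM (1.55) and Gclm, for glutathione synthesis, at 62.2 ± 2.08 against 14.1 ± 1.27 FPKM (2.07). Among the falls of that list, Slc7a11 (-0.56) changed by 0.56 against LPS and was not called without LPS+dNC replicate 2 (-0.43) or 3 (-0.33), and without replicate 1 it was at -0.91. Cell cycle genes rose in 24 and fell in 4 of 29 (0.61, adjusted p = 0.0271, adjusted p = 0.47 with an estimated correlation). Cdk1 was at 8.23 ± 0.8 against 0.983 ± 0.189 FPKM (2.22) and Top2a at 4.23 against 0.443 FPKM (1.86). Against LPS, Cdk1 changed by 0.83 and the NRF2 list lay 0.33 above all genes. The NRF2 list was lost with only the 2 groups fitted (adjusted p = 0.0613) and without genes that share sequence (adjusted p = 0.113). There its median minus all genes was 0.54 and 0.51, in this order. Its adjusted p ranged from 1.58e-05 to 0.113 over all alternatives at the preset correlation. The cell cycle list was lost under quantile normalization (adjusted p = 0.0865), a filter of 5 FPKM (adjusted p = 0.888) and without genes that share sequence (adjusted p = 0.0573), within a range of 0.00238 to 0.888, and where the call was lost its median minus all genes was 0.3, 0.23 and 0.58, in this order.

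Markers of other brain cells rose in the LPS+siAtg5 libraries. All 15 astrocyte markers tested rose, and against LPS as well, including Aldh1l1 (3.58) (median minus all genes 2.51, adjusted p = 0.000103, adjusted p = 0.47 with an estimated correlation). Neuron markers rose in 12 and fell in 0 of 13, such as Stmn2 (2.81) and Dcx (2.99) (1.17, adjusted p = 0.0271, adjusted p = 0.75 with an estimated correlation). That call was lost with a filter of 5 FPKM (adjusted p = 0.06), a pseudocount of 0.1 (adjusted p = 0.117), only the 2 groups fitted (adjusted p = 0.0581) and against LPS (adjusted p = 0.0874). The adjusted p ranged from 0.00245 to 0.117 over all alternatives at the preset correlation. The list's median minus all genes was 2.09 with that filter, 2.08 with that pseudocount, 1.33 with only the 2 groups fitted and 1.12 against LPS. Oligodendrocyte markers rose in 7 and fell in 0 of 8 (Mbp 1.77), and fibroblast, mural and endothelial markers rose in 10 and fell in 2 of 14, with Acta2 at 47.7 against 1.48 FPKM. Border macrophage and monocyte markers rose in 6 and fell in 5 of 13 (Fn1 3.86, Cbr2 -1.73), and of 2 neutrophil and lymphocyte markers Camp rose (0.55) and S100a8 fell (-3.38), which was at 357 ± 255 FPKM in LPS+dNC. Against LPS the changes were 1.73 for Dcx, 0.8 for Mbp, -0.27 for Cbr2, -0.36 for Camp and 1.63 for S100a8, and Camp was at -0.02 under quantile normalization.

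The lists on autophagy and lysosomes were not called with Atg5 knockdown either, but some alternatives called them. The autophagy list (median minus all genes -0.29, adjusted p = 0.066) was called as lower under median-of-ratios scaling (adjusted p = 0.0285), quantile normalization (0.0466), without LPS+dNC replicate 2 (0.0401) or 3 (0.0436) and against LPS (0.0402), within a range of 0.0285 to 0.224. The lysosomal list was called as higher under quantile normalization (adjusted p = 0.0085, range 0.0085 to 0.953). Autophagy genes rose in 19 and fell in 14 of 43 (Ulk2 0.81, Atg4d -1.5), V-ATPase subunits in 10 and 7 of 18 (Tcirg1 -1.25), lysosomal genes in 24 and 11 of 44 (Hexa 1.49, Ctsb -1.19) and respiratory chain genes in 25 and 5 of 37 (Sdha 0.84). Among microglial lists, homeostatic markers rose in 16 and fell in 4 of 23, with the fractalkine receptor gene Cx3cr1 at 13.9 ± 0.765 against 0.177 ± 0.0833 FPKM (3.66) in this comparison and a change of 0.78 against LPS. Disease-associated markers rose in 15 and fell in 5 of 24 (B2m -1.15), and phagocytosis genes in 19 and 10 of 33 (Gas6 3.08). Cholesterol synthesis genes rose in 21 and fell in 0 of 24 (Cyp51 1.39), remyelination-linked factors in 12 and 3 of 19 (Fgf2 3.12), PPAR target genes in 16 and 6 of 25 (Pdk4 1.89) and LXR target genes in 13 and 3 of 18 (Abcg1 3.12, but -1.86 against LPS). Phospholipase A2 and linoleic acid genes rose in 11 and fell in 4 of 18, where Ptgs2, which makes prostaglandins, fell from 116 ± 31.1 to 12.3 ± 0.618 FPKM (-3.1). Stress response genes rose in 15 and fell in 14 of 31 (Nupr1 -2.09) and iron handling genes rose in 12 and fell in 4 of 19 (Steap4 3.16). Against LPS the changes were -0.24 for Atg4d, -0.01 for Ctsb, 0.89 for Hexa, 0.35 for Sdha, -0.51 for B2m, 1.37 for Gas6, 2.4 for Cyp51 and -0.62 for Nupr1. Other lists that were not called became called under some alternatives. Cholesterol synthesis was called as higher under median-of-ratios scaling (adjusted p = 0.0412), without a filter (0.0372), without LPS+dNC replicate 2 (0.0203) and against LPS (2.31e-05), within a range of 2.31e-05 to 0.176. Stress responses were called as lower (5.03e-07, range 5.03e-07 to 0.902) and border macrophage and monocyte markers as lower (0.0402, range 0.0402 to 0.971) against LPS. Respiratory chain genes were called as higher against LPS (0.00284) and under quantile normalization (0.00468), within a range of 0.00284 to 0.938. Homeostatic markers (0.0208, range 0.0208 to 0.618), phagocytosis (0.0345, range 0.0345 to 0.999) and iron handling (0.0373, range 0.0373 to 0.794) were called as higher under quantile normalization. Fibroblast, mural and endothelial markers were called as higher under median-of-ratios scaling (0.028, range 0.028 to 0.351). Adjusted over the list alone, the rises and falls differed for homeostatic markers (16 and 5), stress responses (16 and 14) and neuron markers (13 and 0) and were as given above for the other lists.

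LPS+siAtg5 differed from LPS+dNC in 8988 of 11070 genes (limma with Benjamini-Hochberg adjustment), with 6594 up and 2394 down, and at least 2-fold in 2034 and 530. The share of rises, 73.4%, was 54.1% under median-of-ratios scaling and 50.8% under quantile normalization. Against LPS in place of LPS+dNC 8502 genes were called, 79.7% of them up. Of 27 lists 10 were called by camera at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.091, 4 lists with an unadjusted p under 0.05), and fry called 25. LPS+dNC holds 3 libraries, of which replicate 1 lies apart, and its columns name no unit. All LPS+siAtg5 libraries also held raised astrocyte markers, so the count of 8988 genes cannot be credited to loss of Atg5 alone.

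The remaining named comparison asked what CLA did to LPS-treated microglia. With CLA, interferon-driven genes fell more than with Baf A1, genes of glycolysis and cholesterol synthesis rose, and Il1b rose while Nos2 and Tnf fell. No list call held with an estimated correlation (lowest adjusted p = 0.14). Ifit2 went from 920.5 ± 40.5 (SD, n = 3) to 101 ± 8.72 FPKM (n = 6), a log2 change of -3.18 (SE 0.084, limma adjusted p = 3.64e-18). Rsad2, which encodes the antiviral protein viperin, went from 1459 ± 37.6 to 130 ± 11.9 FPKM (-3.48, SE 0.093, adjusted p = 3.64e-18). Il1b rose from 971.3 ± 87.8 to 2818 ± 695 FPKM (1.51, SE 0.15, adjusted p = 9.23e-09). Nos2 fell from 187 ± 30.3 to 98.8 ± 32.1 FPKM (-0.95, SE 0.16, adjusted p = 1.85e-05) and Tnf from 227 ± 40.3 to 156.5 ± 43.7 FPKM (-0.56, SE 0.13, adjusted p = 0.00107). Arg1, an enzyme of alternatively activated macrophages, rose from 6.95 ± 2.44 to 25.2 ± 4.12 FPKM (1.74, SE 0.47, adjusted p = 0.00282) and Pparg from 0.98 ± 0.344 to 2.57 ± 0.991 FPKM (0.8, SE 0.24, adjusted p = 0.00625). Fads1 (0.05, adjusted p = 0.781) and Fads2 (-0.33, adjusted p = 0.302) were not called, and Atg5 rose by 0.27 (SE 0.047, adjusted p = 2.22e-05).

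The largest rises with CLA were in S100a4 (4.3, 49.2% shared), Igfbp7 (3.28), the dicarboxylate transporter gene Slc13a3 (60.1 ± 9.18 to 575 ± 110 FPKM, log2 change 3.22, SE 0.19, adjusted p = 6.42e-12) and the kinase gene Pim2 (6.57 ± 1.01 to 65.9 ± 4.32 FPKM, 3.15). They were followed by Urah (3.13), Mmp3 (2.9), Fxyd2 (2.89) and Shisa3 (2.76). The largest falls were in Ly6a (-4.41, 31.9% shared), Iigp1 (189 ± 16.4 to 13.3 ± 1.29 FPKM, -3.74), Rsad2, Ifit1bl1 (-3.43), Ly6i (-3.31), Thbs1 (310 ± 36 to 32.1 ± 2.27 FPKM, -3.23), Ifit2 and Cmpk2 (-3.12).

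Several immune gene lists fell with CLA. Interferon-stimulated genes fell in 33 and rose in 1 of 34 (median minus all genes -1.2, camera adjusted p = 1.98e-24, adjusted p = 0.14 with an estimated correlation). Bst2 was again the rise (0.26), and Oas2 went from 108 ± 4.95 to 31 ± 1.37 FPKM (-1.77). Pro-inflammatory mediators fell in 15 and rose in 7 of 34 (-0.35, adjusted p = 0.00777, adjusted p = 0.57 with an estimated correlation). Cd86 went from 36.2 ± 4.79 to 8.37 ± 0.547 FPKM (-1.98) and Cd40 from 114 ± 7.18 to 38.1 ± 3.34 FPKM (-1.55), while Il1b, Cxcl1 (0.99) and Cxcl5 (0.93) were among the rises. Antigen presentation genes fell in 13 and rose in 3 of 17 (-0.41, adjusted p = 1.95e-05, adjusted p = 0.33 with an estimated correlation). Nlrc5 went from 57.7 ± 1.41 to 23.8 ± 1.25 FPKM (-1.25), and H2-Ab1 rose (1.04). The rise of another member, H2-D1 (0.1, adjusted p = 0.0413), turned to -0.04 under median-of-ratios scaling and -0.05 under quantile normalization, and was not called without LPS replicate 1 (0.06). Homeostatic microglia markers fell in 10 and rose in 5 of 23 (-0.25, adjusted p = 0.0249, adjusted p = 0.33 with an estimated correlation). The lipid receptor gene Trem2 went from 18.5 ± 2.37 to 4.83 ± 0.51 FPKM (-1.74) and Fcrls from 39.9 to 157 FPKM (1.9). That list's adjusted p ranged from 0.00907 to 0.142 over all alternatives at the preset correlation. It was lost under quantile normalization (adjusted p = 0.0658), with array weights (adjusted p = 0.1) and without the 3 libraries that lie apart (adjusted p = 0.142). Its median minus all genes was larger under quantile normalization (-0.31) and smaller under the other 2 (-0.15 and -0.14).

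Several metabolic gene lists rose with CLA, and LXR target genes fell. Hypoxia and glycolysis genes rose in 30 and fell in 1 of 33 (median minus all genes 0.98, adjusted p = 1.87e-09, adjusted p = 0.33 with an estimated correlation). Ldha was at 1117 ± 55.9 against 289.5 ± 26.4 FPKM (log2 change 1.95, SE 0.075, adjusted p = 1.23e-15) and Tpi1 at 675 ± 29.1 against 183 ± 25.8 FPKM (1.88). Of 37 respiratory chain genes 36 rose and 0 fell, such as Ndufa4 at 86.6 ± 6.96 against 40 ± 3.79 FPKM (0.42, adjusted p = 8.41e-08, adjusted p = 0.57 with an estimated correlation). Cholesterol synthesis genes rose in 20 and fell in 0 of 24, such as Stard4 (1.24) and Lss (0.81) (median minus all genes 0.5, adjusted p = 0.00178, adjusted p = 0.57 with an estimated correlation). PPAR target genes rose in 18 and fell in 2 of 25 (0.3, adjusted p = 0.0267, adjusted p = 0.57 with an estimated correlation). The lipase gene Lpl was at 165 ± 31.6 against 51.9 ± 8.97 FPKM (1.64), the carnitine carrier gene Slc25a20 at 21.1 against 11.6 FPKM (0.82), and Acsl1 fell (-1.11). NRF2 target genes rose in 14 and fell in 4 of 25, with Akr1b8 at 32.5 ± 1.74 against 5.74 ± 1.08 FPKM (2.33) (0.26, adjusted p = 0.0267, adjusted p = 0.57 with an estimated correlation). LXR target genes fell in 12 and rose in 4 of 18 (-0.58, adjusted p = 0.00669, adjusted p = 0.14 with an estimated correlation). The efferocytosis receptor gene Mertk went from 33.5 ± 4.94 to 11.3 ± 0.827 FPKM (-1.48) and the cholesterol exporter gene Abcg1 from 66.5 to 28.9 FPKM (-1.18). The PPAR list was lost with a filter of 5 FPKM (adjusted p = 0.0568), only the 2 groups fitted (adjusted p = 0.0538) and without genes that share sequence (adjusted p = 0.0759). There its median minus all genes was 0.25, 0.26 and 0.27, in this order. Its adjusted p ranged from 0.00317 to 0.0759 over all alternatives at the preset correlation. The NRF2 list was lost with that filter (adjusted p = 0.0628), only the 2 groups fitted (adjusted p = 0.0614) and without LPS replicate 2 (adjusted p = 0.0505) or LPS+CLA replicate 2 (adjusted p = 0.061), within a range of 0.00306 to 0.0628, and where the call was lost its median minus all genes was 0.21, 0.21, 0.25 and 0.22, in this order.

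Neuron markers, present at low levels, fell in 11 and rose in 1 of 13 with CLA, such as Dcx (-1.07) (median minus all genes -0.72, adjusted p = 0.00669, adjusted p = 0.57 with an estimated correlation). The other lists were not called. Rises and falls numbered 13 and 13 of 43 for autophagy genes, where the cargo receptor Sqstm1 fell from 549 ± 57.3 to 283 ± 19.5 FPKM (-0.95), 5 and 4 of 18 for V-ATPase subunits (Tcirg1 -1.24) and 16 and 17 of 44 for lysosomal genes (Cd68 -1.0). They numbered 6 and 4 of 14 for anti-inflammatory and repair markers, where Il10 rose from 7.64 ± 3.12 to 23.8 ± 2.88 FPKM (1.57), and 7 and 7 of 19 for remyelination-linked factors (Gas6 1.14). Lipid lists had 13 and 1 of 27 for fatty acid synthesis and desaturation (Acot7 2.26) and 7 and 4 of 18 for phospholipase A2 and linoleic acid metabolism (Pla2g7 -1.04). The numbers were 10 and 12 of 24 for disease-associated microglia markers, where Axl fell from 71.2 ± 1.81 to 30.3 ± 2.67 FPKM (-1.21), and 13 and 10 of 33 for phagocytosis (Pros1 1.53). They were 11 and 16 of 31 for stress responses (Pdia4 1.78, Ddit3 -1.33), 8 and 4 of 19 for iron handling (Tfrc 1.23) and 14 and 3 of 29 for the cell cycle (Cdt1 -1.11). For markers of other cells they numbered 2 and 4 of 15 (astrocyte, Aldh1l1 -0.46), 2 and 3 of 8 (oligodendrocyte, Mag 0.7) and 5 and 1 of 14 (fibroblast, mural and endothelial, Kdr -2.01). The last lists had 2 and 3 of 13 (border macrophage and monocyte, Pf4 1.29) and 0 and 0 of 2 (neutrophil and lymphocyte). At the preset correlation, 3 of these lists were called as lower under 1 alternative each. These were autophagy under quantile normalization (adjusted p = 0.0447, range 0.0447 to 0.327), disease-associated microglia markers without LPS replicate 2 (0.0358, range 0.0358 to 0.327) and oligodendrocyte markers without a filter (0.0427, range 0.0427 to 0.454). Of the lists not called, fry called disease-associated microglia markers as lower (adjusted p = 4.39e-05). It called fatty acid synthesis and desaturation (7.26e-07), iron handling (0.000927) and cell cycle genes (0.000598) as higher. Adjusted over the list alone, the rises and falls differed for NRF2 (15 and 4), respiratory chain (37 and 0), antigen presentation (3 and 14) and astrocyte genes (2 and 3). They were as given above for the other lists.

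CLA changed 6981 of 11070 genes (limma with Benjamini-Hochberg adjustment), with 4476 up and 2505 down, and at least 2-fold in 330 and 357. The share of rises, 64.1%, was 49.4% under median-of-ratios scaling and 53.6% under quantile normalization, which moved the median change of all genes from 0.09 to -0.012 and 0.016. Of 27 lists 11 were called by camera at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.14, 3 lists with an unadjusted p under 0.05), and fry called 15. LPS+CLA replicate 2 lies apart from the other 5 libraries and LPS replicate 3 from the other LPS libraries.

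**Figure D3:**
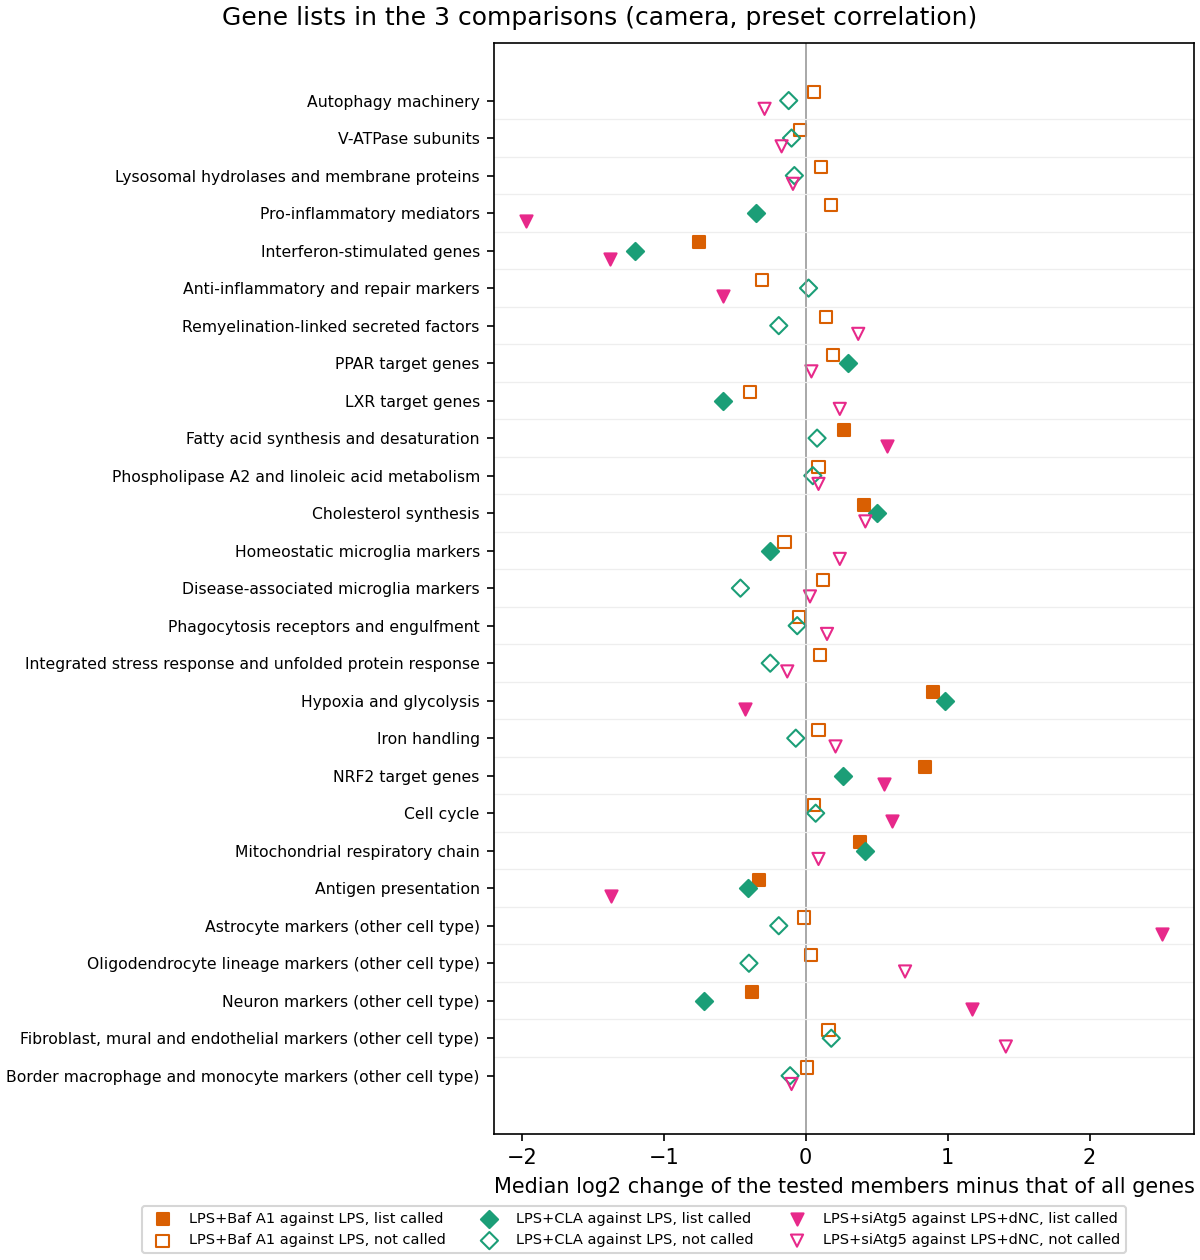
Median log2 change of the tested members of 27 gene lists minus that of all genes (x axis) in the 3 comparisons (symbols), filled where camera called the list at the preset correlation. Interferon-stimulated genes lie at -0.75, -1.2 and -1.38 for Baf A1, CLA and siAtg5, astrocyte markers at 2.51 for siAtg5, and hypoxia and glycolysis genes at 0.9 and 0.98 for Baf A1 and CLA but at -0.43 for siAtg5.

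The Baf A1 and CLA effects were alike across genes. Both raised Il1b, Mmp3, S100a4, Igfbp7 and Ldha and lowered Ly6a, Iigp1, Ifit2 and Oas2. Of 11070 genes 2876 rose and 1716 fell in both, and 357 went opposite ways. At least 2-fold, 109 rose and 156 fell in both. Over all genes, called or not, 77.4% changed with the same sign, where simulated unchanged groups against the same LPS libraries gave 72.3%. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.72 and rho = 0.72, where these simulated groups gave r = 0.65. Their covariance was 0.181 against a simulated 0.00692, a difference of 0.174. The 3 LPS libraries cannot be split into sets of at least 2, so part of the excess over these values may come from the shared controls.

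Set directly against each other, LPS+CLA and LPS+Baf A1 differed in 6016 genes, with 3914 higher and 2102 lower with CLA. The share higher, 65.1%, was 51.1% under median-of-ratios scaling and 53.8% under quantile normalization. The dicarboxylate transporter gene Slc13a3 was at 575 ± 110 FPKM (SD, n = 6) with CLA and 38.2 ± 2.28 FPKM (n = 5) with Baf A1 (log2 change 3.85, SE 0.16, limma adjusted p = 9.87e-14). The complement regulator gene Cd55 was higher by 2.7 and Il10, an anti-inflammatory cytokine gene, by 2.49 (23.8 ± 2.88 against 3.44 ± 0.68 FPKM). Tgfbi (-2.94), Slpi (-2.81, 12.7 ± 6.61 against 88.7 ± 7.65 FPKM) and Susd2 (-2.78) were lower with CLA. Pro-inflammatory mediators were lower with CLA in 26 and higher in 1 of 34 (camera adjusted p = 4.44e-12, adjusted p = 0.15 with an estimated correlation). So were interferon-stimulated genes in 27 of 34, with 3 higher (adjusted p = 9.27e-13, adjusted p = 0.25 with an estimated correlation), and lysosomal genes in 25 of 44, with 6 higher (adjusted p = 1.71e-05, adjusted p = 0.49 with an estimated correlation).

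**Figure D4:**
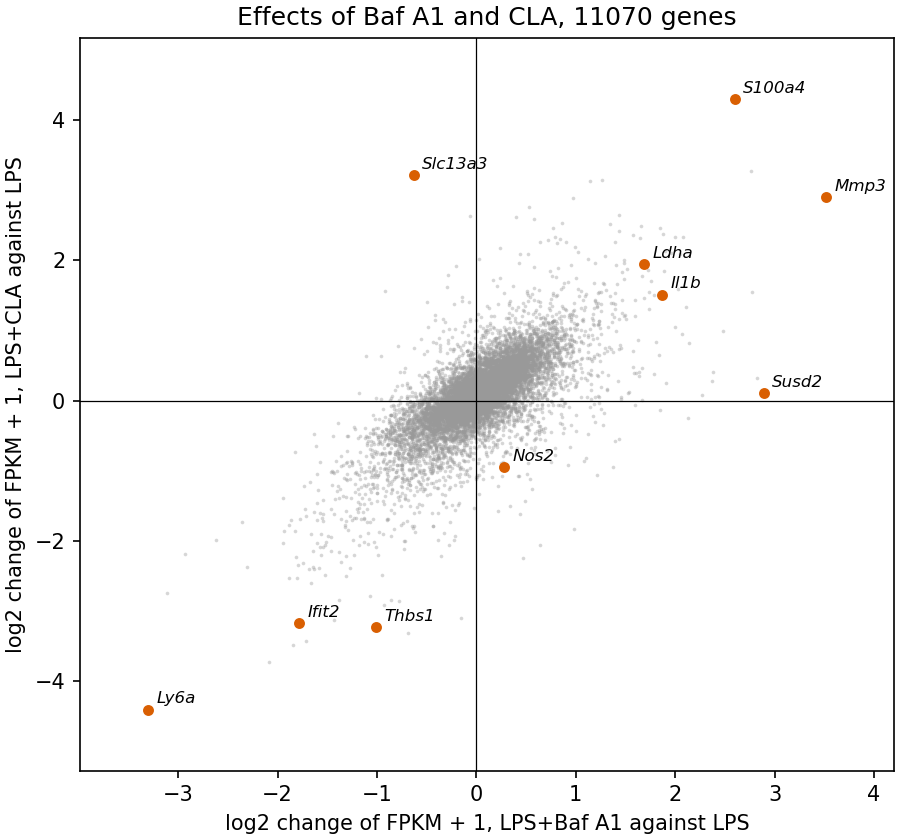
Log2 change of FPKM + 1 with Baf A1 (x axis) and with CLA (y axis), both against LPS, with a point for each of 11070 genes and 10 of the named genes in orange. The points follow a rising band (r = 0.72 across genes), Il1b (1.87 and 1.51) and Ifit2 (-1.79 and -3.18) lie along it, and Susd2 and Slc13a3 lie off it.

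The Baf A1 and siAtg5 effects, which share no library, were only loosely related (r = 0.22, rho = 0.21 across genes), as were those of CLA and siAtg5 (r = 0.25, rho = 0.23). With a pseudocount of 0.1 r was 0.16 and 0.09. Baf A1 and siAtg5 both raised 2405 genes and both lowered 1043, against 2156 and 600 for independent lists, and 1729 went opposite ways, against 2436. The 2 effects themselves differed in 8053 genes, with 2261 higher and 5792 lower for Baf A1. The share higher was 28.1%, and 44.5% under median-of-ratios scaling and 49.6% under quantile normalization, which moved the median difference over all genes from -0.302 to -0.073 and -0.005. The genes Il1b, Il1a and Cxcl3 rose with Baf A1 and fell with siAtg5, while Cxcl5 rose with both (1.17 and 0.66). Il1b differed by 3.18 on the log2 scale (SE 0.21, limma adjusted p = 2.6e-11), Il1a by 5.98 (2.38 with Baf A1 and -3.6 with siAtg5) and Cxcl3 by 6.08 (2.78 and -3.31), and Nos2 by 5.22, Fads2 by -2.69, Fads1 by -1.64 and Gfap by -6.22. For Ly6a (-0.21, adjusted p = 0.462) and Iigp1 (-0.21, adjusted p = 0.17) the difference between the effects was not called. Pro-inflammatory mediators as a list lay 2.26 higher for Baf A1 relative to all genes (camera adjusted p = 4.31e-18, adjusted p = 0.081 with an estimated correlation) and hypoxia and glycolysis genes 1.53 higher (adjusted p = 4.86e-11, adjusted p = 0.24 with an estimated correlation). These differences depend on LPS+dNC as the control of siAtg5. Relative to all genes, pro-inflammatory mediators lay at -1.97 with siAtg5 against LPS+dNC but at -1.2 against LPS. Hypoxia and glycolysis genes lay at -0.43 and -0.13.

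The control groups LPS+dNC and LPS differed in 6329 genes, with 3214 higher and 3115 lower in LPS+dNC. The share higher, 50.8%, turned to 47.1% under median-of-ratios scaling and 46.5% under quantile normalization. Il19 was at 180 ± 67.7 FPKM (SD, n = 3) in LPS+dNC against 1.19 FPKM (n = 3) in LPS (log2 change 6.32), the neutrophil protein gene S100a8 at 357 ± 255 against 8.56 FPKM (5.01) and the lysozyme gene Lyz1 at 140 against 4.74 FPKM (4.63). Rps6 (-5.2), Abcg1 (-4.99) and the matrix metalloproteinase gene Mmp9 (-4.66, 6.24 against 155 FPKM) were lower. Rps6 and Lyz1 share sequence with other genes. Among the lists, pro-inflammatory mediators were higher in 19 and lower in 5 of 34 (camera adjusted p = 0.00859, adjusted p = 0.89 with an estimated correlation). Cholesterol synthesis genes were higher in 18 and lower in 0 of 24 (adjusted p = 3.7e-05, adjusted p = 0.89 with an estimated correlation) and stress response genes in 2 and 23 of 31 (adjusted p = 3.7e-05, adjusted p = 0.46 with an estimated correlation). Antigen presentation genes were higher in 12 and lower in 2 of 17 (adjusted p = 0.00778) and hypoxia and glycolysis genes in 22 and 1 of 33 (adjusted p = 0.00238), both with adjusted p = 0.89 with an estimated correlation. Transfection and any difference in preparation between these groups cannot be told apart.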

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

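All tests of explanations in this part were chosen only after the result was seen, except the one of LPS standing apart from every other group.

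Of 80 values examined, 20 had a library far from the rest of its group by Dixon's test at the 95% level, where chance gives about 5%, or 1 in 20 groups. Only LPS+Baf A1, LPS+siAtg5 and LPS+CLA were examined this way. LPS replicate 3 and LPS+dNC replicate 1, which also lie apart from their groups, could therefore not be flagged. Of the 20 values, 17 were in LPS+CLA replicate 2. Over all 11070 genes such a library was seen for 16.5% of genes in LPS+CLA, with 13.3% at replicate 2, against 5.7% in LPS+Baf A1 and 5.6% in LPS+siAtg5. In FPKM, LPS+CLA replicate 2 was low in Pparg (0.58, others 2.77 to 3.24), Fads1 (4.32, others 7.77 to 8.44), Arg1 (16.84, others 25.99 to 27.68), Slc13a3 (349.87, others 614.76 to 630.69), Pim2 (57.24, others 66.54 to 68.84) and Mmp3 (5.63, others 15.53 to 18.35). It was high in Tnf (245.53, others 135.72 to 143.89), Il1b (4229.67, others 2412 to 2605.07), Nos2 (164.24, others 83.43 to 87.86), Urah (35.3, others 21.08 to 23.19), Ly6a (5.4, others 1.98 to 2.85), Rsad2 (153.91, others 121.85 to 128.35), Ifit1bl1 (70.71, others 46.57 to 52.75) and Ifit2 (118.16, others 94.06 to 100.86). Its median gene was at 2.85 FPKM (others 3.16 to 3.25), 2936 genes were at 0 (others 2127 to 2271) and 9112 reached 1 FPKM (others 9384 to 9414). In LPS+siAtg5, replicate 3 was low in Arg1 (1.41, others 2.38 to 2.47), and replicate 1 was low in Lyz1 (4.09, others 5.43 to 5.79) and high in Olfr1033 (0.32, others 0.01 to 0.02).

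The Baf A1 and siAtg5 effects differed in 8053 genes, more than in any of the 99 other splits drawn (highest 7117). At this number of splits this excludes a chance sorting of the libraries into groups, but not a chance difference between cultures. Of the 8053 genes 1729 were called in opposite directions in the 2 comparisons, 628 up with Baf A1 and down with siAtg5 and 1101 the reverse, and 36 of them changed at least 2-fold both ways. Both counts lie below those of independent lists, 2436 and 52.

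A chance sorting of the libraries can also be excluded for the counts of changed genes with Baf A1 (6395, highest other split 2025 over 56 splits), siAtg5 (8988, highest 5635 over 56), CLA (6981, highest 3042 over 84) and for CLA against Baf A1 (6016, highest 3279 over 100), where 1 split, the real one, reached the count each time. The splits move only these libraries, which may be technical replicates within a group, so chance differences between cultures are not excluded. For LPS+dNC against LPS there are 10 splits, too few for a share under 0.05, with 6329 genes for the real split and 633 for the highest other. For the number of called lists chance cannot be excluded, since 11 of 56 splits gave as many as the 8 with Baf A1 (highest other 9), 4 of 56 as many as the 10 with siAtg5 (highest other 10) and 5 of 84 as many as the 11 with CLA (highest other 15).

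Astrocyte markers rose in LPS+siAtg5 against LPS+dNC. A lower share of microglial RNA alone would raise markers of all other cells alike. Among members at 1 FPKM or more in LPS+dNC, the median change was 3.22 for astrocyte and 1.32 for oligodendrocyte, neuron, fibroblast, mural and endothelial markers (permutation p = 0.02). This cannot decide, since the latter lists include genes also listed for border macrophages, such as Fn1, which rose with Baf A1 too. Homeostatic microglia markers had a median change of 0.58, and of 0.23 against LPS, beside 0.339 and 0.312 for all genes. A separate preparation of LPS+dNC, which the labels do not state, is argued against as the source by a median of 3.22 above all genes with LPS as the control. Astrocytes and other cells carried over from the mixed glia, which shaking should have left behind, stay a candidate source. All 15 tested markers rose against both controls, the abundant Gfap, Clu and Aqp4 included, though 8 of them reached 1 FPKM in LPS+dNC too. This rise does not favour carried-over cells, since expression of these genes by microglia after knockdown would give it as well. The 2 cannot be told apart, because every siAtg5 library carries both the knockdown and the markers (lowest mean log2 level 4.02, highest library of other groups 1.52). What stays open therefore also bears on the other genes that were higher in these libraries, Fads2 and the cell cycle genes among them. Whether it bears on the genes that fell there, Nos2 and Il1b among them, was not tested.

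The Baf A1 and CLA effects were alike. Chance spread between LPS libraries was simulated independently for each gene. It is argued against as the whole cause, since the covariance of 0.181 lay above the highest of 100 simulated values, 0.00747. Deviations shared by many genes or by whole cultures were not simulated, so they are not covered. If the LPS libraries stood apart from all groups, genes changed alike should also differ that way between LPS and both LPS+dNC and LPS+siAtg5, and this held for 43% (exact 95% interval 37% to 49.2%) of the 265 genes changed at least 2-fold the same way, against 32.8% of all genes called in both. That share was under the bound of 50% set beforehand, but LPS+dNC decided it, with 46.8% called alike and 26% the opposite way, whereas 90.2% were called alike in LPS+siAtg5. The bound took both groups as sound comparators, and the LPS+dNC columns are in doubt, so LPS standing apart cannot be told apart from a common effect. A batch shared by the Baf A1 and CLA libraries cannot be told apart from a common effect for these 265 genes, because the labels give no batch. A common action of Baf A1 and CLA stays open as a biological explanation.

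LPS+dNC differed at least 2-fold from all 4 other groups in 363 genes. Of these, 22.3% share over 20% of their sequence with another gene, against 12.2% of all tested genes. Among genes at which another group stood apart the share was 6.8% of 950 for LPS+siAtg5 (Fisher's exact p = 5.24e-14), 0% of 25 for LPS+Baf A1 (p = 0.0039), 6.7% of 30 for LPS (p = 0.0593) and 19.1% of 47 for LPS+CLA (p = 0.711). The LPS+CLA columns name FPKM in their headers like the others, so a raised share does not single out another gene model or rule for shared reads behind the LPS+dNC columns, in which Plin2 also had 2 differing values. LPS+siAtg5 was transfected too, so transfection alone would not set LPS+dNC apart from that group at these genes. Such a difference, another batch and a transfection effect that knockdown undid cannot be told apart, also for the 282 with little shared sequence. No other group was transfected without the Atg5 siRNA.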

How the results depend on the processing

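The alternatives without the 3 libraries that lie apart, without genes that share sequence and with LPS as the control of LPS+siAtg5 were chosen after seeing the data, and the others were planned. All counts of changed genes stayed within 1.5 times of the values given, at 5341 to 7311 for Baf A1 (5659 to 6429 without 1 library), 6593 to 11355 for siAtg5 (8623 to 8845), 5767 to 7832 for CLA (6371 to 7130), 5915 to 9911 for the difference between the Baf A1 and siAtg5 effects, 4996 to 7300 for CLA against Baf A1 and 5304 to 7269 for LPS+dNC against LPS. Lists called numbered 7 to 8, 10 to 12 and 10 to 11 without 1 library, 0, 0 and 0 with an estimated correlation, and 18 (Baf A1) and 25 (siAtg5) with fry, which asks another question. The correlation of the CLA and siAtg5 effects was 0.3 with a filter of 5 FPKM, and with a pseudocount of 0.1 the correlations were 0.7 (Baf A1 and CLA), 0.16 (Baf A1 and siAtg5) and 0.09 (CLA and siAtg5). The share of rises depended on the scaling, as given beside each count. Of 409 values of genes named by the rule, members of lists that were not called included, 399 kept their direction and side of the threshold under median-of-ratios scaling. There, Xaf1 (-0.11), Stat6 (-0.09) and Atp6ap1 (-0.01) with siAtg5 and H2-D1 (-0.04) with CLA reversed, and under quantile normalization Fth1 (0.39) and Camp (-0.02) with siAtg5 and H2-D1 (-0.05) with CLA did. With LPS as the control of LPS+siAtg5, 106 of 141 kept both, 10 were no longer called, and 25 reversed: Il19 (0.24), Lyz1 (0.13), Olfr1033 (0.1), Xaf1 (-0.15), Igf1 (-0.22), Mrc1 (-0.93), Clec7a (-0.31), Mlxip (0.05), Bnip3 (0.01), Slc7a11 (0.56), E2f1 (0.29), Tyms (0.51), Atg12 (0.12), Pdgfb (0.49), Abcg1 (-1.86), Mylip (-1.11), Mertk (0.01), Ptgs1 (-0.37), Sars (-0.33), Fbxl5 (0.31), Cox5b (0.31), Cox6a1 (0.45), Flt1 (0.39), Camp (-0.36) and S100a8 (1.63). The cause was not tested. Without the 3 libraries that lie apart 7067, 9098 and 7483 genes changed with Baf A1, siAtg5 and CLA, and without genes that share sequence 5578, 7895 and 6106, from fewer genes tested. Same-numbered libraries did not deviate together (correlations of -0.11 to 0.09, and not every library correlated best with its own number). No pairing by number was seen, but control groups of 3 libraries cannot exclude it. With the replicate number as a block 6031, 8761 and 6449 genes were called. Depth is unknown, so low values cannot be graded by counting error.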

Other observations

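Of 17 genes of protein folding, translocation or degradation at the endoplasmic reticulum, outside the fixed lists, 16 could be compared. They were chosen after the stress response list was seen to go both ways, and no enrichment was tested. With Baf A1 the chaperone and disulfide isomerase genes P4hb (407 against 156 FPKM, log2 change 1.38), Hyou1 (1.43), Calr (959 against 413 FPKM, 1.21), Pdia6 (1.34), Manf (1.24) and Pdia3 (0.9) were higher than with LPS alone, and all 16 rose. With CLA 15 of 16 rose, including P4hb (1.4), Calr (1060 against 413 FPKM, 1.35) and Pdia6 (1.49), and Syvn1 was not called (-0.09, adjusted p = 0.0888). With siAtg5 15 rose and 1, Syvn1, fell (-0.91).

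Target genes of ATF4, the transcription factor of the integrated stress response, went both ways. With Baf A1, Trib3 fell from 18.8 to 8.04 FPKM (-1.13), Ddit3 from 153 to 69.6 FPKM (-1.12) and Atf3 from 168 to 98.2 FPKM (-0.75), whereas the amino acid synthesis and transport genes Psat1 (1.22), Phgdh (0.94) and Slc7a11 (1.27) rose. Of the 23 such genes in the stress response list, 6 rose and 12 fell with Baf A1 (median log2 change -0.4), 4 rose and 16 fell with CLA (-0.43), and 8 rose and 13 fell with siAtg5 (-0.29). The endoplasmic reticulum genes had medians of 0.92, 0.8 and 0.73, and all genes 0.039, 0.09 and 0.339. No test of a difference between these 2 sets is given, because the sets were chosen from the pattern itself.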
